A study of Mus musculus with 6 samples.

How the data were processed

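Gene expression was measured by RNA sequencing in 6 libraries of mouse embryonic fibroblasts, 3 transfected with a negative control siRNA and 3 with an siRNA against Hk2. Per the labels' protocols, RNA was extracted with Trizol, messenger RNA was enriched with oligo(dT) beads, fragmented and reverse transcribed with random hexamers, and the libraries were circularised and sequenced as DNA nanoballs on a BGI platform. The protocol in the labels describes strand marking with dUTP as an option, and whether these libraries were counted by strand is not given in the sources used here. Reads of overlapping and antisense genes may therefore not have been separated.

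The deposited values are TPM, rounded to 2 decimals, in 1 table of 22355 rows with a column per library; every column sums to the same total over the table, within rounding. The genome build was GRCm39 (mm39) per the submitters' processing notes. The aligner, the counting tool and the annotation release are not given in the sources used here. The table holds 16784 protein-coding rows, 5566 long non-coding RNA (lncRNA) rows and 5 of other types, with coordinates and with GO and KEGG annotation; the annotation cells of 2584 rows (GO) and 19 rows (KEGG pathways) were not used here. No column pair held identical values. TPM is scaled to a fixed total in each library and keeps no depth, so the depth is unknown, no counting interval or detection floor could be given, and a change in a few abundant genes shifts all others. The 3 siHk2 columns match sample titles. The siControl columns carry numbers that match no sample title, so they were taken as replicates of the control group without an identity of their own. The titles number both groups alike, so whether the libraries are paired is unknown.

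Genes with a mean of at least 1 TPM over the 6 libraries were tested (13341 genes). The group difference was fitted on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. No covariate was used. The pseudocount of 1 means that log2 fold changes understate the change of low genes. Fold changes called "times" are ratios of mean TPM. Levels are given as mean ± SD over the libraries of a group.

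Gene lists were tested with camera from limma, with its preset correlation of 0.01 between genes, on the same values, adjusted over the lists with at least 5 tested members; camera with an estimated correlation and fry were run beside it. Members were also adjusted over each list alone. The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. KEGG and GO terms with 15 to 300 tested genes were tested in the same way, adjusted within each source, with all tested genes as background.

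Named genes were the hexokinases; the 10 largest rises and 10 largest falls in log2 fold change among genes with a symbol, an adjusted p under 0.05, a mean of at least 5 TPM and groups that do not overlap, leaving out predicted genes; and up to 4 members with the smallest p in each described list. Members named beyond this to spell out a small count, and Gapdh, Cd68, Eng and Des, were chosen after their values were seen. Values of some single genes are not reported here.

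The tests were checked on simulated data made from the real means and spreads of this comparison, with 13341 genes. Of 100 genes changed by a log2 fold change of 1, 74% were recovered, and of 100 changed by 0.5, 50%; 3.88% of the calls were false. All 10 shifted lists and 1 of 40 unshifted lists passed in camera. The simulated data took over means and spreads but no correlation between genes. They therefore cannot give the error rates, for genes or for lists, where genes are correlated. Over the 12 real lists that passed in camera, the estimated correlation ran from -0.003 (fatty acid oxidation and lipid droplets) to 0.601 (cholesterol synthesis and uptake).

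For sequence features, the longest annotated transcript and 3' UTR of each gene were taken by gene identifier from the GENCODE M21 reference, which is on the older build GRCm38, and no coordinate was taken from it. A transcript was found for 97.5% of the tested genes. For the listed and named genes, 775 in all, the share of 50-base windows that also occur in a transcript of another gene was counted, pseudogenes included, and for 40 it was 50% or more. All 7-base sequences present in the 3' UTRs of at least 50 of 11497 genes (16221 sequences) were tested for association with the log2 fold change in a linear model with UTR length and GC content, with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 in Python 3.11.15. This scan was checked on shuffled fold changes, where 0 sequences passed, and on a planted fall of 0.1, which it ranked 1 and estimated at -0.11. Figures were drawn with matplotlib 3.10.9.

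Alternatives to the settings were a pseudocount of 0.1 or 0.5, no filter or a mean of at least 5 TPM, quantile normalization, scaling by trimmed means, rescaling without mitochondrially encoded genes and the 20 most abundant genes, moderation without the trend, library weights, protein-coding genes alone, and leaving out each library in turn. A covariate from the residuals and a test without genes that carry GAGACT in the 3' UTR or have no usable annotated 3' UTR were added after the data were seen. A named gene that lost its call in 5 or more of the settings is given with their number. Tests on read counts were not run, because the deposited values are TPM.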

Results

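RNA was sequenced from mouse embryonic fibroblasts (MEFs), connective tissue cells grown from mouse embryos, after transfection with a small interfering RNA (siRNA) against Hk2 or with a negative control siRNA. An siRNA is a short double-stranded RNA that guides the cleavage of transcripts matching it. Hk2 encodes hexokinase 2, which phosphorylates glucose at the entry to glycolysis. The design asks which transcripts differ between cells treated with the Hk2 siRNA (siHk2, 3 libraries) and cells treated with the control siRNA (siControl, 3 libraries). The control columns of the deposited table carry the numbers 4, 5 and 6 and the siHk2 columns the numbers 1, 2 and 3, and libraries are named by these numbers. No liver sample was analysed here, although the title of the series speaks of liver.

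Transcript levels were deposited as TPM, in which length-corrected transcript values are scaled to the same total in every library; the unit keeps no record of sequencing depth, so the depth of each library is unknown. Between 18419 and 18757 genes per library had a TPM above 0, and between 13230 and 13471 reached a TPM of 1. The 13 mitochondrially encoded genes held 7.42% to 8.36% of the TPM, and the 20 genes with the highest mean 14.1% to 14.96%. Across genes, libraries of the same group correlated at r = 0.986 to 0.991 on the log2(TPM + 1) scale and libraries of different groups at r = 0.981 to 0.987; genes are not independent replicates. The first principal component (38.5% of the variance) separated the groups. The second (25.7%) ran across both of them, with siControl library 5 at -17.8 and siHk2 library 2 at -13.7 against 17.6 for siControl library 6 and 11.97 for siHk2 library 1. Nothing states that the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

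Hk2 itself was lower in every siHk2 library. Its level was 59.5 ± 2.78 TPM in siControl (SD, n = 3) and 21.9 ± 0.469 TPM in siHk2 (SD, n = 3), 63.2% lower. On the log2(TPM + 1) scale it fell by 1.40 (SE 0.0553, 95% confidence interval -1.53 to -1.27, adjusted p = 0.000222 in limma with Benjamini-Hochberg adjustment). Single libraries read 57.1, 62.5 and 58.9 TPM in siControl and 22.4, 21.4 and 21.8 TPM in siHk2. Hk2 (ENSMUSG00000000628) lies on the minus strand of chromosome 6, from 82702006 to 82751435 in the deposited table, whose build is GRCm39 per the submitters' processing notes.

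The other tested hexokinases did not pass the threshold. Hk1, the most abundant hexokinase transcript in both groups, was at 101 ± 10.6 TPM in siControl and 90.2 ± 6.72 TPM in siHk2 (SD, n = 3, adjusted p = 0.281). Hk3 was at 8.04 ± 0.306 and 7.28 ± 1.05 TPM (adjusted p = 0.470). Hkdc1, a hexokinase-like gene beside Hk1, was at 1.89 ± 0.282 and 0.947 ± 0.218 TPM (adjusted p = 0.0852) with no overlap between the groups. Adjusted over the list alone, 2 of the 4 tested hexokinases were lower, Hk2 and Hkdc1 (adjusted p = 0.0347 for Hkdc1). That list holds Hk2, the target of the siRNA, whose small p eases the adjustment of the other members. It is therefore no separate support for a fall of Hkdc1, and the groups did not overlap for 35.7% of all tested genes.

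**Figure D1:**
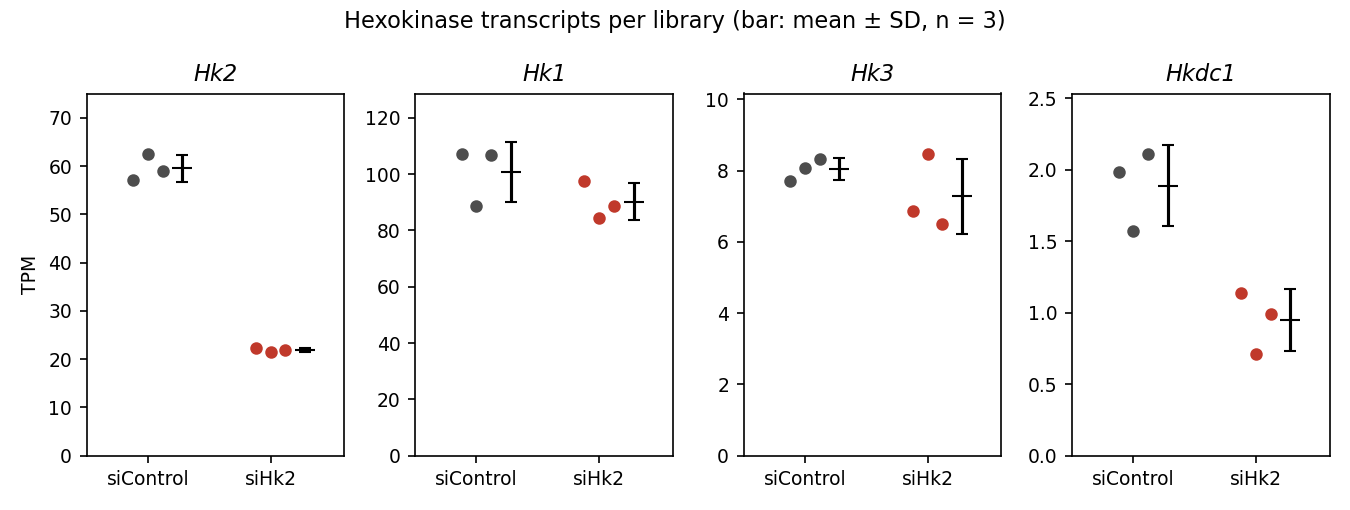
TPM of Hk2, Hk1, Hk3 and Hkdc1 (vertical axes, linear, from 0) in each library (points) of the siControl and siHk2 groups, with the mean and SD of the 3 libraries beside them. Hk2 lies between 57.1 and 62.5 TPM in siControl and between 21.4 and 22.4 TPM in siHk2, while the points of Hk1 and Hk3 overlap between groups.

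Across the transcriptome, 12 of 37 gene lists stood apart in camera: those of replication and mitosis genes were lower in siHk2, and 10 lists, among them histones, lipid metabolism, the respiratory chain and matrix genes, were higher. The smallest value over these lists was adjusted p = 0.0923 with an estimated correlation, so 0 passed that test. Of 13341 genes tested, 1810 (13.6%) passed an adjusted p of 0.05 in limma, 820 higher and 990 lower in siHk2. Most changes were small: 402 of them reached an absolute log2 fold change of 0.5 (229 higher, 173 lower) and 62 reached 1 (52 higher, 10 lower). The groups did not overlap for 4760 genes (35.7%, where chance gives 10%). The number of genes past the threshold fell to 506 without siHk2 library 3, 662 without siControl library 4, 720 without siHk2 library 2 and 866 without siHk2 library 1. It was 1057 without a mean-variance trend, 1186 with no filter on low values and 4040 with library weights.

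The largest rise among genes with a mean of at least 5 TPM was that of H2bc4, a core histone H2B gene, from 33.0 ± 5.54 to 166 ± 11.7 TPM (SD, n = 3), with a log2 fold change of 2.30 (SE 0.12, adjusted p = 0.000289). H1f2, a linker histone gene, rose from 86.0 ± 17.1 to 227 ± 10.8 TPM. Lrg1, which encodes a secreted leucine-rich glycoprotein, rose from 2.36 ± 1.36 to 11.2 ± 3.62 TPM. Cox8b, a tissue-restricted subunit of cytochrome c oxidase, went from 8.07 ± 1.17 to 28.6 ± 1.54 TPM, and Aqp7, a channel for water and glycerol, from 4.08 ± 0.216 to 13.8 ± 1.10 TPM. Angpt4, an angiopoietin, was 3.04 times higher in siHk2 on the TPM scale. The other rises in this set were those of Treml1, a platelet receptor (3.03 times), Comp, a cartilage matrix protein (2.70 times), Nr4a1, a nuclear receptor of the immediate early response (2.62 times), and Cmbl, a hydrolase (2.39 times). Their adjusted p-values in limma ran from 0.000289 for H2bc4 to 0.0243 for Treml1, whose call was lost in 5 of 18 settings. For H2bc4, 30.1% of the 50-base windows of its longest transcript also occur in transcripts of other genes, so its level is uncertain.

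After Hk2, the largest fall was that of Syngr2, a vesicle membrane protein, from 209 ± 13.1 to 84.8 ± 2.63 TPM (SD, n = 3), with a log2 fold change of -1.29 (SE 0.0556, adjusted p = 0.000222). Slbp, whose product binds the stem-loop of histone mRNAs, fell from 46.4 ± 1.09 to 22.6 ± 0.433 TPM (adjusted p = 0.000289). The tetraspanin gene Tspan3 fell from 45.9 ± 1.59 to 21.1 ± 1.58 TPM, and Chst14, a dermatan sulfotransferase gene, from 21.5 ± 2.21 to 9.87 ± 1.04 TPM. The metallothionein gene Mt2 (8.88 to 3.82 TPM), the sialyltransferase gene St6gal1 (11.6 to 4.95 TPM), Rtl10 (13.1 to 6.14 TPM), the Abl interactor gene Abi2 (9.98 to 4.68 TPM) and Ap3s1, a subunit of the AP-3 adaptor (190 to 99.6 TPM), made up the remaining falls, with adjusted p-values up to 0.0369; 31.8% of the 50-base windows of Ap3s1 occur in other genes. Of these 9 genes other than Hk2, 7 (Syngr2, Tspan3, St6gal1, Chst14, Slbp, Abi2 and Ap3s1) carry the sequence GGAGACT in an annotated 3' untranslated region (UTR), against 13.4% of the tested genes with such a region; this sequence was picked by a scan on the same fold changes. Mt2 and St6gal1 lost their calls in 6 and 7 of the settings tried.

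**Figure D2:**
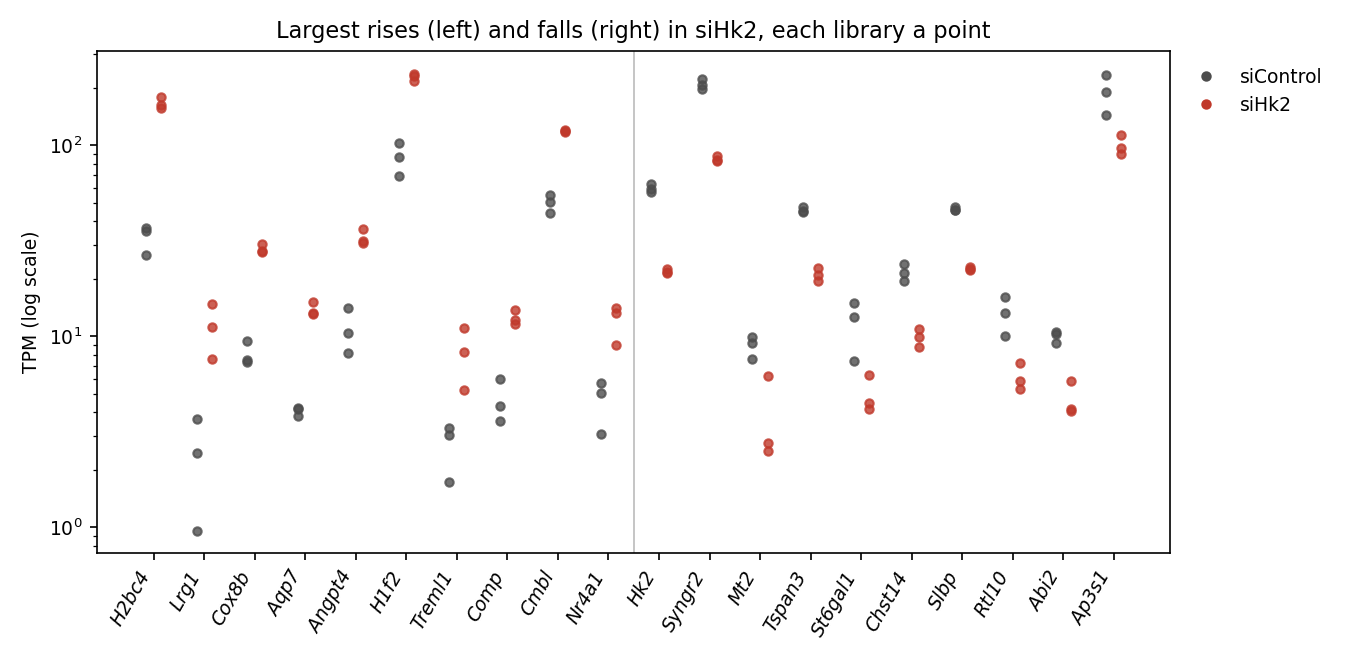
TPM (vertical axis, log scale) of the 10 genes with the largest rise (left) and the 10 with the largest fall (right) in siHk2, with each of the 3 siControl and 3 siHk2 libraries as a point. H2bc4 goes from a mean of 33.0 to 166 TPM and Hk2 from 59.5 to 21.9 TPM, and the libraries of the groups do not overlap for any gene shown.

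Genes of DNA replication and mitosis were lower in siHk2. Of 35 tested genes of the S phase, 30 fell and none rose, with a median log2 fold change of -0.47. Mcm3, a subunit of the replicative helicase, fell from 175 ± 4.57 to 115 ± 1.46 TPM (SD, n = 3), and Cdt1, which loads that helicase, from 128 ± 6.17 to 80.6 ± 0.834 TPM. Uhrf1, which couples replication to DNA methylation, fell from 255 ± 9.29 to 169 ± 4.03 TPM. Tk1, E2f2, Pcna, Ccne2 and Rfc4 did not pass; E2f2 was the member with a positive value (26.5 and 31.0 TPM). Adjusted over the list alone, 31 fell. The list stood lower than other genes in camera (adjusted p = 2.11e-23), and adjusted p = 0.0923 with an estimated correlation.

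Of 36 tested genes of the G2 and M phases, 33 fell and none rose, with a median log2 fold change of -0.42 and all 36 below 0. Foxm1, a transcription factor of mitotic genes, fell from 121 ± 4.97 to 79.1 ± 1.34 TPM. The kinase gene Aurkb fell from 120 ± 7.23 to 83.3 ± 2.92 TPM, the kinesin gene Kif2c from 62.8 ± 2.21 to 43.7 ± 1.79 TPM and the spindle gene Ckap2l from 113 ± 5.54 to 74.8 ± 3.53 TPM. Cdk1, Nusap1 and Cdc25c did not pass over all genes, and 36 fell adjusted over the list alone. In camera the adjusted p was 2.69e-24, and adjusted p = 0.243 with an estimated correlation. Of the 71 members of both lists, 23 carry the 6-base core GAGACT in the 3' UTR; their median log2 fold change was -0.46, against -0.42 for the 48 without it. In the same siHk2 libraries the glial marker S100b and the epithelial marker Krt7 were higher.

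Histone transcripts, as captured in these poly(A)-selected libraries, moved the other way. Of 14 tested replication-dependent histone genes, whose messages normally end in a stem-loop in place of a poly(A) tail, 9 rose and none fell, with a median log2 fold change of 1.11. Besides H2bc4 and H1f2, H3c8 rose from 14.2 ± 2.68 to 31.3 ± 3.61 TPM and H2bc8 from 1.38 ± 0.181 to 7.08 ± 2.16 TPM (SD, n = 3). H4c8, H3c3, H4c1, H3c6 and H2ac13 did not pass, each at a mean below 4 TPM in both groups. H2bc6 (0.797 to 2.46 TPM) and H1f5 (0.957 to 3.31 TPM) rose at similarly low levels, and reached the filter through their siHk2 values. H4c8 (0.913 and 3.61 TPM), H4c1 (0.76 and 2.81 TPM) and H2ac13 (0.927 and 1.37 TPM) also reached it that way, and H3c6 (1.18 and 0.9 TPM) through siControl. For such genes the sign largely follows from the filter, yet they count in the list's median and camera test. Of 30 listed histone genes with deposited values, 14 reached the filter. Adjusted over the list alone, 10 rose. In camera the adjusted p was 2.24e-07, and adjusted p = 0.243 with an estimated correlation. The libraries were made from poly(A)-selected RNA per the labels, which favours the histone messages that carry a tail. Whether total histone message rose or fell therefore cannot be told. Histone genes also share sequence (54.1% of the 50-base windows of H3c8 and 49.7% of those of H2bc8 occur in other genes), so single levels are uncertain. Slbp, which also sits on the list of S phase genes, fell in the same libraries, and it carries GGAGACT in its 3' UTR.

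Some genes that take up, burn or store fatty acids rose. Of 26 tested genes of fatty acid oxidation and lipid droplets, 8 rose and none fell (13 rose adjusted over the list alone), with a median log2 fold change of 0.24. Acadm, the medium-chain acyl-CoA dehydrogenase, rose from 174 ± 14.8 to 289 ± 18.5 TPM (SD, n = 3, adjusted p = 0.00241). The fatty acid transporter Cd36 rose from 120 ± 1.99 to 180 ± 4.94 TPM, the binding protein Fabp5 from 110 ± 13.02 to 167 ± 1.79 TPM and the thiolase Acaa2 from 209 ± 14.6 to 252 ± 3.84 TPM, a call lost in 5 of 18 settings. In camera the list had an adjusted p of 2.67e-07, and adjusted p = 0.0923 with an estimated correlation.

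Of 24 tested genes of fatty acid and triglyceride synthesis, 8 rose and none fell (13 rose adjusted over the list alone; median log2 fold change 0.25). Acacb, an acetyl-CoA carboxylase, rose from 25.7 ± 1.36 to 37.9 ± 1.31 TPM, Agpat2, an acyltransferase of glycerolipid synthesis, from 34.4 ± 2.50 to 49.6 ± 3.97 TPM, and the acyl-CoA synthetase Acsl4 from 51.8 ± 0.895 to 65.5 ± 2.37 TPM. Dgat1, which makes triglycerides, was 1.25 times higher. In camera the adjusted p was 2.43e-06, and adjusted p = 0.312 with an estimated correlation. Of 22 tested genes of cholesterol synthesis and uptake, 7 rose and none fell (10 adjusted over the list alone; median 0.18), among them Hsd17b7 (38.1 ± 1.14 to 55.7 ± 2.02 TPM), Insig1 (363 ± 43.9 to 485 ± 19.0 TPM), Ebp and Acat2. The camera adjusted p of this list was 6.01e-06, and adjusted p = 0.479 with an estimated correlation. For Acat2, 45.9% of the 50-base windows occur in other genes.

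Markers of adipocytes and chondrocytes included 4 that rose among 8 tested, with none lower (median log2 fold change 0.35): Comp, Lpl, the lipase that releases fatty acids from lipoproteins (501 ± 88.5 to 894 ± 64.3 TPM, SD, n = 3), Cidec, a lipid droplet protein (3.18 ± 0.512 to 8.93 ± 2.29 TPM), and Pparg, the nuclear receptor of fat cell differentiation (122 ± 6.23 to 151 ± 5.00 TPM). Adjusted over the list alone, 4 rose and 1 fell. The camera adjusted p was 0.00330, and adjusted p = 0.243 with an estimated correlation.

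Some nuclear genes of mitochondrial energy metabolism rose by small amounts, while most did not pass. Of 38 tested nuclear genes of the respiratory chain, 9 rose, none fell and 29 did not pass (20 rose adjusted over the list alone), with a median log2 fold change of 0.15. Ndufv1 and Ndufa10 of complex I rose from 164 ± 8.39 to 207 ± 12.2 TPM and from 172 ± 7.36 to 210 ± 2.15 TPM (SD, n = 3), and Uqcrq of complex III from 183 ± 11.02 to 225 ± 1.146 TPM. The camera adjusted p was 1.37e-06, and adjusted p = 0.312 with an estimated correlation. None of the 13 mitochondrially encoded genes passed in limma, with 0 also adjusted over the list alone and 1 at an unadjusted p under 0.05; their median was 0.04 and their camera adjusted p 0.364. The sequences of mt-Co2, mt-Co3, mt-Atp6, mt-Nd4l and mt-Nd3 recur almost whole elsewhere in the annotation, which leaves their levels uncertain. Of 32 tested genes of pyruvate dehydrogenase and the tricarboxylic acid (TCA) cycle, 7 rose, 1 fell (Dld, a call lost in 5 settings) and 24 did not pass, with the same counts of rises and falls adjusted over the list alone (median 0.15). Idh1, a cytosolic isocitrate dehydrogenase, rose from 272 ± 9.47 to 345 ± 6.56 TPM, Suclg2 from 74.6 ± 3.11 to 96.7 ± 1.69 TPM, and Sdha from 241 ± 3.95 to 287 ± 5.35 TPM. The rises on this list thus include cytosolic enzymes, Idh1 and Mdh1, whose call was lost in 6 of 18 settings. In camera this list had an adjusted p of 0.000114, and adjusted p = 0.427 with an estimated correlation.

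Few genes of glucose use below hexokinase passed the threshold. Of 19 tested glycolysis genes, Aldoa rose (1901 ± 31.2 to 2122 ± 60.9 TPM, SD, n = 3) and Eno1 fell (912 ± 36.2 to 773 ± 35.8 TPM), while 17 did not pass. Adjusted over the list alone, 1 fell. At an unadjusted p under 0.05 there were 8 of the 19, against 30.7% of all tested genes. The mixed form of fry counts moves in either direction and does not compare a list with other genes. It gave this list an adjusted p of 0.000427, so small changes both ways are not excluded. The call of Aldoa was lost in 9 of 18 settings and that of Eno1 in 5. The list's camera adjusted p was 0.877, in the lower direction although its median (0.028) and mean (0.012) log2 fold changes lay above 0. For Eno1, 72.2% of the 50-base windows occur in other genes. Gapdh was listed at 20.3 ± 1.22 and 22.2 ± 4.47 TPM, low beside Aldoa, and 27.2% of its windows occur in other genes, so its level is uncertain. None of 5 tested glucose and lactate transporters passed in limma over all genes, with 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.511); the main glucose transporter gene Slc2a1 was at 127 ± 14.9 and 110 ± 14.6 TPM (adjusted p = 0.278). In the pentose phosphate pathway, Rpia and H6pd rose among 12 tested genes, with 2 also adjusted over the list alone (camera adjusted p = 0.703; median -0.01, mean 0.039 and direction higher). Among 16 genes of hexosamine and nucleotide sugar synthesis 1 rose and 1 fell (Galk1), and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.364). The calls of H6pd, Rpia and Galk1 were lost in 7, 6 and 5 settings.

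Ugp2, Gbe1 and Pcx rose among 14 tested genes of gluconeogenesis and glycogen, with 3 also adjusted over the list alone (median log2 fold change 0.12). Gbe1, the glycogen branching enzyme, went from 78.8 ± 6.98 to 103 ± 4.54 TPM. The camera adjusted p was 0.0392, and adjusted p = 0.490 with an estimated correlation. This call was lost in 6 of 18 settings, where the adjusted p reached 0.161, and that of Pcx was also lost in 6.

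Some matrix and antigen presentation genes rose. Of 30 tested collagen and matrix genes, 12 rose and none fell (13 adjusted over the list alone; median log2 fold change 0.20). The basement membrane collagen genes Col4a2 and Col4a1 rose from 310 ± 6.84 to 455 ± 3.70 TPM and from 317 ± 13.7 to 418 ± 5.59 TPM (SD, n = 3). Fbln2 rose from 114 ± 6.70 to 169 ± 8.43 TPM and the fibrillin gene Fbn1 from 41.8 ± 1.40 to 59.7 ± 1.51 TPM. The camera adjusted p was 4.94e-05, and adjusted p = 0.243 with an estimated correlation. Psmb8, an immunoproteasome subunit (18.4 ± 2.41 to 26.7 ± 1.67 TPM), H2-Q4 and H2-D1 rose among 15 tested antigen presentation genes, 4 adjusted over the list alone (median 0.17). The camera adjusted p was 0.00187, and adjusted p = 0.243 with an estimated correlation. The class I genes H2-Q4 and H2-D1 share 22.0% and 14.3% of their 50-base windows with other genes, and their calls were lost in 6 and 7 settings.

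**Figure D3:**
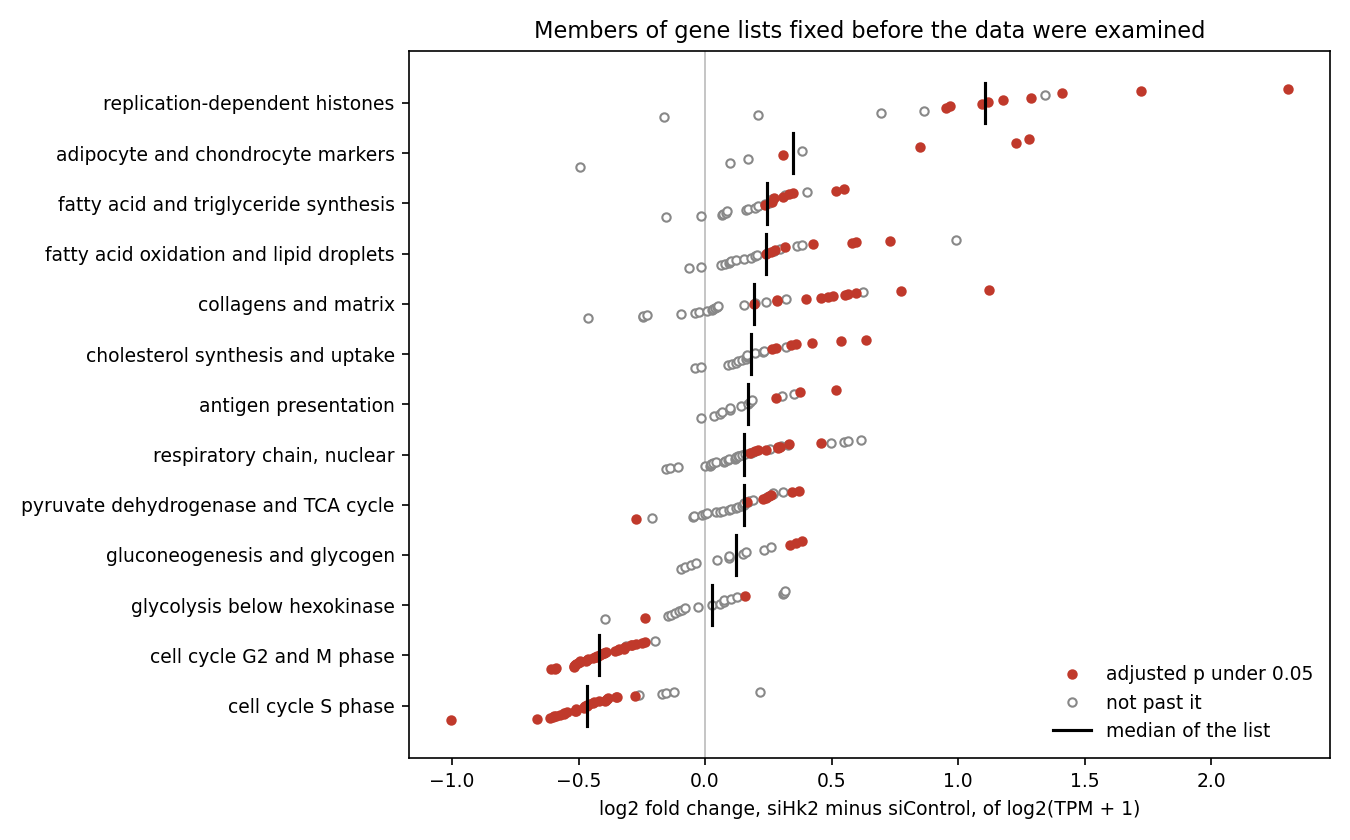
Log2 fold change (horizontal axis, siHk2 minus siControl on log2(TPM + 1)) of each tested member (points) of the 12 gene lists past an adjusted p of 0.05 in camera and of glycolysis below hexokinase. Filled points passed an adjusted p of 0.05 in limma, open points did not, and the vertical line is the median of the list, from -0.47 for S phase genes to 1.11 for replication-dependent histones.

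Lists were tested where at least 5 members were measured. With an estimated correlation in camera, 0 of the 37 passed and 7 had an unadjusted p under 0.05. With fry, 15 passed. It tests whether members move one way on balance and does not compare a list with other genes. In its mixed form, which counts moves in either direction, 32 of the 37 passed. Where the mixed form is not named, fry means the one-way form. Cholesterol synthesis and uptake (fry adjusted p = 0.0767) and gluconeogenesis and glycogen (fry adjusted p = 0.0745) passed in camera but not with fry. The ferroptosis, matrix protease, TGF-beta, autophagy and serine lists passed with fry but not in camera. Stress, death and inflammation lists did not stand apart in camera. Of 28 tested genes of the integrated stress response, Cth, Nupr1 and Ddit4 rose and Asns, Slc7a5, Atf4 and Shmt2 fell (4 rose and 6 fell adjusted over the list alone; camera adjusted p = 0.364). Each of these 7 calls was lost in several settings: Shmt2 in 11 of 18, Atf4 in 9, Nupr1 in 8, Cth, Ddit4 and Asns in 7 each and Slc7a5 in 6. Dnajb9 rose and Hsp90b1 and Pdia4 fell among 22 chaperone genes of the endoplasmic reticulum (2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.309), and Cryab rose while Hsp90ab1, Hsp90aa1 and Hsf1 fell among 14 cytosolic heat shock genes (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.414). The calls of Hsf1, Cryab and Pdia4 were lost in 9, 7 and 5 settings. Aifm2, a suppressor of ferroptosis, rose from 17.8 ± 2.50 to 37.6 ± 3.47 TPM (SD, n = 3). Acsl4 and Gpx4 also rose in this list of 17, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.199); 61.7% of the windows of Gpx4 occur in other genes, as do 58.5% of those of Hsp90aa1. Mgst1 was the gene that rose among 28 antioxidant targets of NRF2, with 1 also adjusted over the list alone (camera adjusted p = 0.511).

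Among 22 tested p53 targets Ccng1, Ei24 and Btg2 rose and Gtse1 and Bax fell (3 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.753). Bmf rose and Bak1 and Bax fell among 23 apoptosis genes (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.753, direction lower with a mean of 0.012). Ifit3 rose from 2.65 ± 0.317 to 6.41 ± 0.232 TPM (SD, n = 3) among 23 interferon response genes, 1 also adjusted over the list alone (camera adjusted p = 0.199), and 51.2% of its 50-base windows occur in other genes. Tnfaip2 fell among 18 NF-kappaB and cytokine genes, 1 adjusted over the list alone (camera adjusted p = 0.423), and Txnip rose among 12 inflammasome genes, 1 adjusted over the list alone (camera adjusted p = 0.364). Plod2 and Ddit4 rose and Egln3 fell among 21 HIF-1 targets outside glycolysis, 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.997, direction lower with a mean of 0.023). Bax, Txnip and Ddit4 lost their calls in 7 settings each, Btg2, Tnfaip2 and Egln3 in 6 each and Ei24 in 5.

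Ccn1, Lmod1, Tgfbr1 and Skil rose and Tgfb1 fell among 18 tested genes of TGF-beta signalling and myofibroblasts (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0884). Lmod1 (0.68 to 2.00 TPM) reached the filter through its siHk2 values. Adamts2 and Ctsk rose and Ctsb and Mmp19 fell among 18 matrix proteases and inhibitors (6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.121). Of 36 autophagy and lysosome genes, Pink1, Lamp2, Lamp1, Gabarapl2 and Map1lc3a rose and Ctsb, Wipi1, Tfe3 and Atg12 fell (9 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0946). Of 23 genes of serine, glycine and one-carbon metabolism, 2 rose, Aldh1l1 among them, and Ahcy, Shmt1, Mthfd1, Mthfd1l and Shmt2 fell (2 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.157); 77.0% of the windows of Ahcy occur in other genes. Nr4a1 and Btg2 rose and Myc fell among 25 immediate early genes (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.703). Rpl21 and Rpl12 fell among 48 ribosomal protein genes, with 0 adjusted over the list alone (camera adjusted p = 0.877). Among 19 genes of the small RNA machinery and common reference genes, Sdha rose and Actb and Ywhaz fell (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.545); Actb fell from 4647 ± 261 to 3725 ± 46.5 TPM. Many of these calls were lost in other settings: Shmt2 in 11, Rpl12 in 10, Ywhaz in 9, Rpl21 and Skil in 8 each, Map1lc3a, Tfe3, Atg12, Aldh1l1 and Myc in 7 each, Tgfbr1, Mmp19, Lamp1 and Btg2 in 6 each, and Lamp2, Gabarapl2 and Mthfd1l in 5 each.

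The fibroblast markers Fbln2 rose and Vim fell (2365 ± 51.2 to 1969 ± 58.5 TPM, SD, n = 3) among 10 tested, 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.199). Of 17 tested markers of macrophages and blood, endothelium, epithelium and liver, skeletal muscle and neural cells, 2 rose and 0 fell. S100b went from 90.2 ± 2.56 to 143 ± 6.78 TPM, and Krt7 from 1.55 ± 0.521 to 5.31 ± 0.825 TPM. The macrophage marker Cd68 (44.0 and 36.9 TPM), the endothelial marker Eng (268 and 259 TPM) and the muscle marker Des (95.3 and 97.4 TPM) did not pass. Skeletal muscle was the sole one of these groups with enough tested members for camera, 6, of which 0 passed in limma and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.511).

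Annotation terms carried by the deposited table again placed DNA replication lower and fatty acid metabolism and oxidative phosphorylation higher, and added RNA processing among the lower ones. Of 300 tested KEGG pathways, 44 passed in camera, 32 higher and 12 lower in siHk2, and of 1017 Gene Ontology (GO) terms 166 passed, 53 higher and 113 lower. With an estimated correlation in camera 0 terms passed (32 KEGG and 109 GO terms had an unadjusted p under 0.05), the smallest being adjusted p = 0.310 with an estimated correlation for KEGG and adjusted p = 0.352 with an estimated correlation for GO. Among the lower KEGG pathways were DNA replication (23 of 35 tested genes fell and 1 rose, adjusted p = 6.68e-12), the spliceosome (30 of 127 fell and 0 rose, adjusted p = 7.72e-07) and nucleocytoplasmic transport (21 of 99 fell and 1 rose, adjusted p = 3.37e-05). For the spliceosome this became adjusted p = 0.310 with an estimated correlation, and for the other two adjusted p = 0.411 with an estimated correlation. Higher pathways included oxidative phosphorylation (29 of 122 rose and 1 fell, adjusted p = 1.12e-09), fatty acid metabolism (13 of 52 rose and 0 fell, adjusted p = 4.97e-08), degradation of valine, leucine and isoleucine (16 of 45 rose and 1 fell, adjusted p = 1.69e-06) and PPAR signaling (15 of 50 rose and 0 fell, adjusted p = 1.91e-06). None of these 4 passed with an estimated correlation: adjusted p = 0.411 with an estimated correlation for fatty acid metabolism, the lowest of them, and adjusted p = 0.628 with an estimated correlation for degradation of valine, leucine and isoleucine, the highest.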

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

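The residual covariate and the run without genes that carry GAGACT in the 3' UTR or have no usable one were chosen after the results were seen; the other alternatives were fixed before. The Hk2 level in siHk2 against siControl stayed lower and past the threshold in all 17 alternatives that tested it, with log2 fold changes from -1.44 to -1.37 (-1.43 to -1.37 when 1 library was left out). The count of 1810 changed genes (820 higher, 990 lower, 62 with an absolute log2 fold change of at least 1) moved more. With no filter on low values it was 1186 (501 higher), where 22355 genes shared the adjustment. Without the mean-variance trend it was 1057 (484 higher, 573 lower). With library weights it was 4040 (2032 higher, 2008 lower, 122 by at least 1). With a covariate for the first residual component it was 3391 (1742 higher, 1649 lower), including all 1810. Without genes that carry GAGACT or have no usable 3' UTR it was 1160 (592 lower, 36 by at least 1), with 7439 genes tested; the 2 removals were not run apart. With a mean of at least 5 TPM, 35 genes changed by at least 1, since low genes were left out. For the trend and the weights the cause was not tested. The covariate was taken from the residuals of the same group fit. It therefore left the fold changes as they were and took up residual spread by construction, so its higher count is no separate check on the calls. Leaving out 1 library gave 506 to 2129 changed genes, 193 to 1023 higher, 313 to 1106 lower and 39 to 88 changed by at least 1, with fewer samples in each. The total was 662 without siControl library 4, 866 without siHk2 library 1, 720 without siHk2 library 2 and 506 without siHk2 library 3, of which 652, 823, 704 and 496 were among the 1810. The 3 other scalings gave 1756 to 1832 genes and moved the median of all genes by under 0.1. Of 37 gene lists 12 passed, and 11 to 14 did so when 1 library was left out. With an estimated correlation in camera, 0 lists, 0 KEGG pathways and 0 GO terms passed (7, 32 and 109 at an unadjusted p under 0.05). Of the 12 lists, gluconeogenesis and glycogen alone lost its camera call in other settings of the fit (6 of 18). Among 216 further named genes that passed, 629 of 3806 combinations of gene and alternative lost the call, none changed sign, and 86 genes never lost it. No paired analysis was possible because the control columns carry numbers found in no sample title, so whether the libraries are paired is unknown. Tests on read counts, planned if the table held counts, were not run. TPM hides the depth of each library, so which low genes were limited by depth cannot be told.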

Other observations

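The tests of more cells in S phase and of less Slbp were set after the values they rest on had been seen, and the genes of the next paragraph were picked after their values were seen. The split of the cell cycle genes by GAGACT rests on a sequence picked by a scan of the same fold changes.

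Of 1742 tested lncRNA genes, 68 rose, 32 fell and 1642 did not pass, with a median log2 fold change of 0.072. Of 11598 protein-coding genes, 752 rose and 958 fell; the difference in balance was not tested. Neat1, the scaffold RNA of nuclear paraspeckles, rose from 73.2 ± 5.96 to 136 ± 4.17 TPM (SD, n = 3, adjusted p = 0.000722 in limma). Malat1, another abundant nuclear RNA, was at 89.9 ± 12.2 and 129 ± 22.3 TPM (adjusted p = 0.0551) and did not pass. Among protein-coding genes, the selenium carrier Selenop rose from 122 ± 0.834 to 244 ± 20.9 TPM (adjusted p = 0.000522). The GO term glutathione peroxidase activity was higher, with 9 of 17 tested genes up (camera adjusted p = 0.000561, and adjusted p = 0.431 with an estimated correlation).

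The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1810 genes, 1 split (the real one) reached that number, and the highest of the others called 1 gene. Every other split puts libraries of both groups on each side. The group difference then adds to the spread within a side, so few calls there follow from the design.

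Lower log2 fold changes in siHk2 went with a short sequence in 3' UTRs, the region through which the seed bases of an siRNA guide can lower unintended transcripts. Of 16221 7-base sequences, GGAGACT was most strongly tied to lower log2 fold change (t = -11.51, adjusted p = 2.85e-26; lowest t over 100 shuffles -5.29, permutation p = 0.0099, the smallest they can give), and it occurs 1 time in the 5513-base Hk2 transcript, as do 26.0% of the sequences tested. In this linear model 5 sequences passed in the lower direction and 3 in the higher (ATATTTA, AATCATA and AATATTT, adjusted p 0.0312 to 0.0471). The model counts genes as independent units, although all fold changes come from the same 6 libraries. The median log2 fold change was -0.09 for 249 genes with GGAGACTA, -0.04 for 1295 with GGAGACT but not GGAGACTA, -0.021 for 468 with GAGACTA but not GGAGACT, 0.005 for 2046 with the core GAGACT alone and 0.01 for 7439 with none. GGAGACT was present in 20.7% of the genes called lower against 12.8% of the others, and in 32.2% of those called lower by at least 0.5 against 13.2%; as the sequence was picked on the same fold changes, these shares describe the scan's result and are no further evidence. A candidate explanation is that seed pairing of the Hk2 siRNA lowered part of these transcripts directly, apart from the loss of hexokinase 2; the siRNA sequence is not known here, a change in an endogenous microRNA was not tested, and 753 genes called lower lack the sequence against 196 that carry it.

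The cell cycle lists were lower in siHk2, with a median log2 fold change of -0.44 over their 71 tested members. The tables argue against scaling between libraries and against GC content or length bias as the whole cause: the median was -0.443 or lower under 3 other scalings and -0.448 after a trend on transcript GC content and length was removed. Direct seed pairing in the members' own 3' UTRs also leaves most of it. The 48 members without GAGACT, the core of the sequence picked on these fold changes, had a median of -0.422. Cells of another type in the siHk2 cultures cannot be told apart from the treatment: of 5 types tested for this, the glial marker S100b reached 142.99 TPM, above the bound of 50 set beforehand, which ignored its 90.2 TPM in controls, and markers of adipocytes and chondrocytes, not among the 5, were higher as a list in camera (adjusted p = 0.00330, and adjusted p = 0.243 with an estimated correlation; Lpl 501 to 894 TPM). Fewer dividing cells, from the loss of Hk2 or from other targets of the siRNA, may underlie the fall and stays untested.

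Histone transcripts captured after poly(A) selection were higher while the S phase genes were lower. More cells in S phase would raise the S phase genes too, and that list had a median of -0.468. Less complete poly(A) selection in siHk2 cannot be told apart, since the 3 other transcripts without a standard tail (Terc, Malat1 and Gm26464, median 0.372) include 1 with a mean of at least 5 TPM. They went both ways (Malat1 0.514, Terc 0.372 and Gm26464 -0.711) and none passed the threshold. Terc (2.09 and 2.91 TPM, SE 0.367) and Gm26464 (2.20 and 1.11 TPM, SE 0.421) were low, so their signs carry little weight. Neat1, the nuclear RNA that rose past the threshold (log2 fold change 0.888), was not counted among them. These values thus do not speak against less complete selection. That less Slbp left more histone messages with a poly(A) tail cannot be told apart either: the replication-dependent histones lay 1.216 above 7 replacement histones, whose messages do not need Slbp, but most of that gap is the histone rise itself (median 1.106), poly(A) selection would give it too, and the replacement histones went both ways (H3f3a rose, Macroh2a1 and H2az2 fell; median -0.11). Whether Slbp fell through its GGAGACT was not tested, and S phase genes without that sequence also had a median of -0.461.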
